A study of Mus musculus with 9 samples.

How the data were processed

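Open chromatin was measured by bulk ATAC-seq in 9 libraries of D2A1-d cells, a mouse breast carcinoma line, in 3 groups of 3: a non-targeting control hairpin (NTC) and the hairpins shMed1 #2 and shMed1 #4. Per the labels' protocols, cells were transduced with the hairpins, and washed cells were tagmented with the Nextera transposase for 1 h at 37 °C. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with BWA to mm10 (GRCm38), and peaks were called with MACS2 and counted with featureCounts from Subread. Tool versions, the removal of duplicate or mitochondrial reads, how peaks of the libraries were merged, and whether the transposase offset was applied are not given in the sources used here.

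The deposited values are a signal per peak, named by the authors as DESeq2-normalized counts, that is, read counts divided by a size factor per library. The table held 75936 peaks of 501 bases on chromosomes 1 to 19 and X. In every library 100% of the values were whole multiples of a common step, within 0.01 of a whole number, so the size factor and the reads of each peak could be worked out. The size factors ran from 0.799 to 1.22, and the reads in peaks from 34.8 to 53.7 M per library. Reads outside peaks were not analysed here, so the share of reads in peaks is not known. The step could not be checked against a peak with 1 read, since the lowest nonzero values stood for 2 or more reads. Count models in edgeR and DESeq2 were therefore not run, and limma on log2 values was the main test.

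Log2 of the value plus a pseudocount of 1 was tested for peaks with a mean of at least 10 over the 9 libraries, with no further scaling. This left 75930 peaks and removed 6. A limma fit with trend (limma 3.58.1, R 4.3.3, data.table version 1.17.8) held a mean for each of the 3 groups. Its contrasts were #2 against NTC, #4 against NTC, the mean of both hairpins against NTC, and #4 against #2. P-values were two-sided and adjusted by Benjamini-Hochberg over the peaks of a contrast, with a threshold of 0.05. Errors of log2 fold changes are limma's standard errors, and errors of group means are SDs with n = 3. On simulated data, 50 peaks were moved per fold. The fit recovered 40% at a fold of 1.25, 74% at 1.5, 94% at 2 and 84% at 0.5, with 4 false calls. The adjusted threshold depends on the share of changed peaks, which was far smaller there than in the data. These percentages thus do not measure recovery in the data.

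The annotation held no strand, so transcription start sites could not be told from the other end of a gene. A peak whose centre lay within 1 kb of either annotated end of a protein-coding gene was called a gene-end peak, which replaced the planned promoter class. Other peaks went to the gene body they lay in, or to the nearest gene end within 50 kb (intergenic), and the rest stayed unassigned. Of the 75936 peaks, 12227 were gene-end, 35093 gene-body, 20519 intergenic and 8097 unassigned, and 15762 of 21631 protein-coding genes had a peak. An assigned gene is the nearest by these rules and not a tested target. Coordinates are printed as deposited, and whether they start at 0 or 1 is not stated. No genome sequence was used, so transcription factor motifs and GC content were not analysed here.

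Groups, contrasts, the main tests, most alternatives, the gene lists and the rule for naming peaks were fixed before the data were examined. Choices made later include the gene-end class and 3 added alternatives: voom weights on the worked-out reads, thinning of reads to the smallest library, and assignment of peaks to the nearest gene end. The comparisons by peak strength, the counts over other splits of the 6 libraries of a pair of groups, and the tests on neighbouring peaks and on single genes with many peaks were also added later. The rule named, for each hairpin, the peaks past the threshold with a mean of at least 50 and all 3 hairpin libraries on the same side of all 3 NTC libraries, ranked by fold change. The first 10 higher and 10 lower were taken, with 1 peak per gene and at most 5 unassigned peaks each way. The first 5 each way were taken for the mean of both hairpins and for #4 against #2. Each list gave at most 2 higher and 2 lower peaks with the smallest adjusted p in the mean of both hairpins, and all peaks of Med1 and Med4 were named. Some peaks that the rule names are not reported here.

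The 20 lists held 510 gene entries, of which 506 matched the annotation. They covered AP-1 and immediate early genes, integrins and focal adhesion, extracellular matrix, mesenchymal regulators and markers, epithelial markers, mammary luminal and basal identity, TGF-beta and BMP signalling, YAP and TEAD targets, dormancy-linked genes, nuclear receptors and their targets, the Mediator complex, cell cycle, ribosomal protein genes, interferon response, NF-kappaB and inflammatory genes, p53 targets, the unfolded protein and integrated stress response, and markers of blood, of endothelium and fat, and of neural cells. Lists were tested with camera from limma, at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 20 lists of a contrast. Peaks of a list were also adjusted over the list alone.

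Both hairpins share the 3 NTC libraries, which adds covariance to their fold changes. The overlap of their calls was set beside 20 simulations of unchanged groups that shared controls in the same way, with noise independent for each peak and library. The mean log2 value of gene-end peaks minus that of other peaks was compared between groups by exact two-sided permutation tests over libraries, where 3 against 3 cannot go below 0.10 and 6 against 3 cannot go below 0.0119. Alternatives were other pseudocounts and filters, equal totals, quantile and cyclic loess scaling, quality weights, fits of the compared groups only, a block on the replicate number, each library left out in turn, and the added ones. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.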

Results

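Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 9 libraries of D2A1-d mouse breast carcinoma cells. The series belongs to a study of the Mediator subunit MED4 and metastatic dormancy. These libraries address what lowering Med1 does to open chromatin. MED1 and MED4 are subunits of Mediator, the coactivator complex that links transcription factors to RNA polymerase II. Cells carried a non-targeting control (NTC, n = 3), shMed1 #2 (n = 3) or shMed1 #4 (n = 3). The labels call the libraries of a group biological replicates without describing the cultures, so the p-values measure only the spread between these samples.

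Reads in peaks were 46.4, 44.7 and 40.9 M in NTC, 50.3, 37.7 and 53.7 M in #2, and 42.6, 34.8 and 38.7 M in #4. The median peak held 162 to 252 reads per library. Totals of the normalized values were 41.3 ± 0.155 M in NTC, 43.9 ± 0.391 M in #2 and 43.4 ± 0.296 M in #4 (SD, n = 3). Across peaks, log2 values of libraries of the same group correlated at r = 0.988 to 0.991, and those of different groups at 0.970 to 0.982. The first principal component held 38.2% of the variance and ordered the groups as NTC, #4 and #2. The second held 22.0% and set #4 apart from both other groups.

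**Figure D1:**
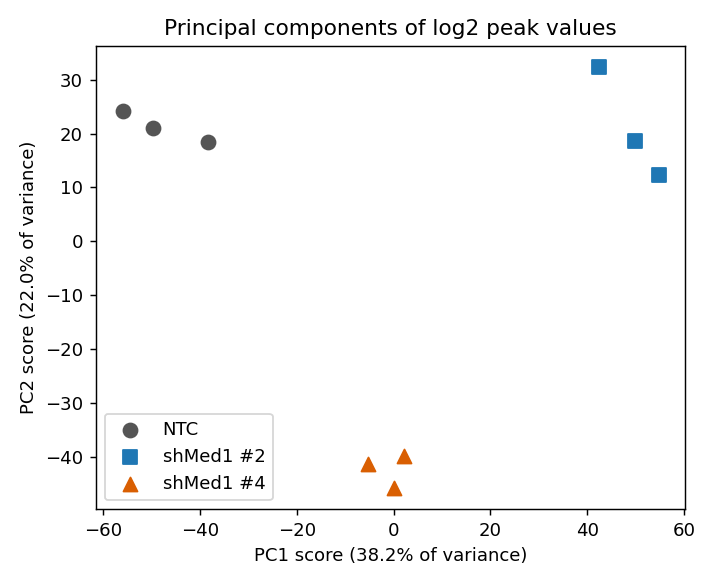
Scores of the 9 libraries on the first principal component (38.2% of the variance, x axis) and the second (22.0%, y axis) of log2 peak values. Each point is a library, and the 3 libraries of NTC, shMed1 #2 and shMed1 #4 lie apart from those of the other groups.

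The targeted gene was examined first. Med1 had a gene-end peak (chromosome 11, 98192989 to 98193490) at 2114 ± 41.3 normalized counts in NTC, 2023 ± 143 in #2 and 1971 ± 73.1 in #4 (SD, n = 3). Its log2 fold change in the mean of both hairpins was -0.08 ± 0.04 (limma, adjusted p = 0.132), so it did not pass. It did pass as lower with equal totals (-0.16, adjusted p = 0.0026), quantile scaling (-0.17, 0.00103), cyclic loess (-0.19, 0.000469), quality weights (-0.10, 0.0467), and without shMed1 #2 replicate 1 (-0.11, 0.0382). A Med1 gene-body peak (chromosome 11, 98182116 to 98182617) had a log2 fold change of 0.13 ± 0.11 (adjusted p = 0.367). Hairpins act on the transcript, so accessibility cannot show whether Med1 was depleted. At Med4 the gene-end peak (chromosome 14, 73509727 to 73510228) fell from 691 ± 7.96 in NTC to 527 ± 38.0 in #2 and 545 ± 71.1 in #4 (SD, n = 3). Its log2 fold change was -0.37 ± 0.07 (limma, adjusted p = 3.88e-05), while an intergenic Med4 peak (chromosome 14, 73474725 to 73475226) was at -0.06 ± 0.11 (adjusted p = 0.705).

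With shMed1 #2, the peaks that rose most included a gene-body peak of Map3k4, a stress-activated MAP kinase kinase kinase (chromosome 17, 12266568 to 12267069). It went from 167 ± 19.2 normalized counts in NTC to 482 ± 38.0 (SD, n = 3), a log2 fold change of 1.53 ± 0.11 (limma, adjusted p = 2.08e-16). An intergenic peak near Dnajb1, which encodes an HSP40 cochaperone (chromosome 8, 83616659 to 83617160), rose by 1.49 ± 0.17. Peaks assigned to Tktl1, a transketolase-like protein, Ndufa10, a subunit of respiratory complex I, Ralgapa2, a RAL GTPase-activating protein, Hes1, a Notch-responsive repressor, Runx2, an osteogenic transcription factor, Rad51b, a recombination factor, and Ccdc15 rose by 1.42 to 1.51. An unassigned peak (chromosome 6, 127375630 to 127376131) rose by 1.77 ± 0.10. Among peaks that fell, a gene-body peak of Daam1, a formin that nucleates actin (chromosome 12, 71850059 to 71850560), went from 86.5 ± 3.09 to 30.5 ± 7.37, a log2 change of -1.50 ± 0.23 (limma, adjusted p = 4.17e-07). Peaks assigned to Csmd3, Nckap5, Filip1l, and Nid2, a basement membrane nidogen, had log2 changes between -1.51 and -1.44, and those of 4 unassigned peaks ran from -1.58 to -1.39.

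In all, 17928 of 75930 peaks rose and 14781 fell with #2 (43.1%), with a median absolute log2 change of 0.41 among them, a fold of 1.32. A log2 change of at least 1 was reached by 444 of them, 275 higher and 169 lower. The share of higher calls was 54.8%, but 37.9% with equal totals (13498 higher and 22132 lower). Equal totals moved the median of all peaks to -0.10, so the balance of gains and losses depends on the scaling.

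With shMed1 #4, the Dnajb1 peak rose most: it went from 65.9 ± 3.56 in NTC to 242 ± 107 (SD, n = 3), a log2 fold change of 1.77 ± 0.17 (limma, adjusted p = 2.36e-11). A peak near Hs6st2, a heparan sulfate sulfotransferase (chromosome X, 51697666 to 51698167), rose by 1.65 ± 0.25, and the peak near Rad51b (chromosome 12, 79872492 to 79872993) by 1.63 ± 0.16. A peak inside Itga9, which encodes an integrin alpha chain (chromosome 9, 118888570 to 118889071), rose by 1.51 ± 0.13, and a peak inside Tln2, a talin that couples integrins to actin, by 1.49 ± 0.22. Peaks assigned to Utp14b, Kcnf1, a potassium channel subunit, Abcb9, a lysosomal peptide transporter, Ermard and Myrfl rose by 1.39 to 1.48. Among peaks that fell, a Gas7 gene-body peak (chromosome 11, 67679902 to 67680403) changed by -1.41 ± 0.28 (limma, adjusted p = 9.24e-05). Peaks assigned to Gm46900, Paxbp1, Fcer2a, the low-affinity IgE receptor, Cert1, a ceramide transfer protein, and Atxn1 changed by -1.18 to -1.12, and 4 unassigned peaks by -1.57 to -1.22. Without shMed1 #4 replicate 2 the change at Paxbp1 went from -1.16 to -0.76 (adjusted p = 0.018).

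In all, 13150 peaks rose and 9152 fell with #4 (29.4%), with a median absolute log2 change of 0.35 among them, a fold of 1.28. A log2 change of at least 1 was reached by 199 of them, 153 higher and 46 lower. The share of higher calls was 59.0%, but 38.4% with equal totals (9329 higher and 14938 lower). The 9152 that fell became 5500 without NTC replicate 3 and 5819 without NTC replicate 2.

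Both hairpins moved many of the same peaks. 9330 peaks rose with both, where independent calls would give 3105, and 5909 fell with both, where they would give 1782. The latter became 3193 without NTC replicate 3 and 3658 without NTC replicate 2. Dnajb1, Rad51b, Hs6st2, Itga9 and Ermard rose most in the mean of both hairpins, by 1.63, 1.53, 1.47, 1.31 and 1.28 on the log2 scale. A peak near Hsf2, a heat shock transcription factor (chromosome 10, 57463261 to 57463762), and a peak inside Atxn1 (chromosome 13, 45623615 to 45624116) changed most among assigned peaks that fell, by -1.22 ± 0.22 and -1.16 ± 0.18. The shared peaks were 46.6% of the #2 calls and 68.3% of the #4 calls. Of these, 61.2% were higher, but 35.9% with equal totals (6030 higher and 10751 lower) and 49.2% with quantile scaling (7380 higher and 7616 lower).

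Across peaks, which are not replicates, the fold changes of both hairpins correlated at r = 0.597, against 0.501 in 20 simulations of unchanged groups that shared the NTC libraries. Their covariance was 0.0608, which is 0.0495 above the simulated 0.0113, and 75.6% of peaks had the same sign, against 66.6%. In those simulations limma called at most 0 peaks the same way in both hairpins, and 904 on average at an unadjusted p under 0.05, against 20295 in the data. The simulated noise was independent for each peak and library, whereas real peaks of a neighbourhood moved together. A joint deviation of the NTC libraries was thus not simulated, and these simulated counts can be too low. Part of the excess overlap may come from the shared controls, since 3 NTC libraries cannot be divided with 2 or more on each side, and r ran from 0.559 to 0.644 when any library was left out.

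**Figure D2:**
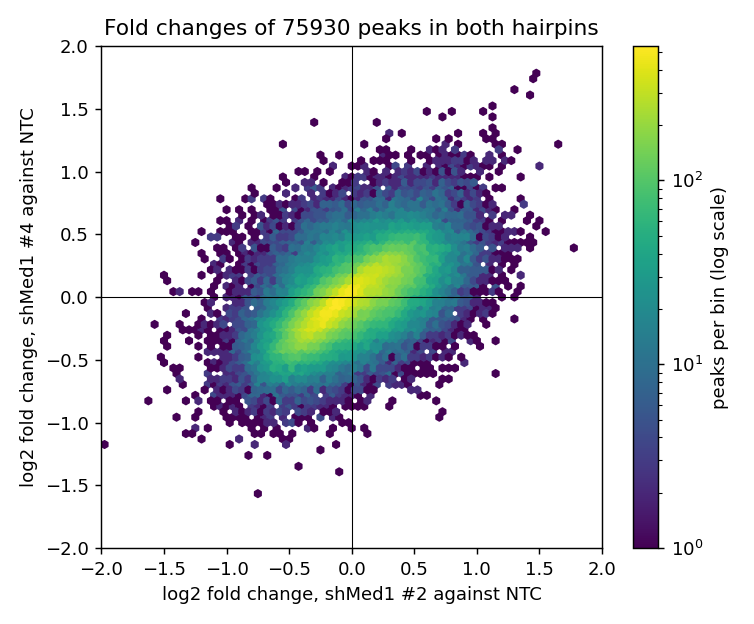
Log2 fold changes against NTC of 75930 peaks with shMed1 #2 (x axis) and shMed1 #4 (y axis), with color for the number of peaks per bin on a log scale. Fold changes of both hairpins correlated at r = 0.597, against 0.501 in simulated unchanged groups with shared controls.

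In the mean of both hairpins, 16796 peaks rose and 13452 fell (39.8%), with a median absolute log2 change of 0.34. The share of higher calls was 55.5%, but 36.6% with equal totals (12104 higher and 21010 lower), and 8325 fell without NTC replicate 3. The gene groups below refer to this contrast, with n = 3 in each of the 3 groups and log2 fold changes ± SE. A camera call, where given, is at the preset correlation. Lists were not matched on peak strength, and on place only in the runs on gene-end peaks alone. Since strong peaks away from gene ends mostly rose (below), a list call may reflect the strength and place of its peaks. With an estimated correlation camera called 0 of the 20 lists in each of the 4 contrasts, and 0 lists had an unadjusted p under 0.05.

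Of 440 peaks of integrins and focal adhesion genes, which tie the cytoskeleton to the matrix, 150 rose and 49 fell (153 and 50 adjusted over the list alone), and 116 and 71 with equal totals. Gene-body peaks of Tns1, a tensin (chromosome 1, 74028732 to 74029233), and Bcar1, the adhesion docking protein p130Cas (chromosome 8, 111726353 to 111726854), rose by 0.57 ± 0.04 and 0.49 ± 0.04. The gene-end peak of Itga5, a fibronectin receptor chain (chromosome 15, 103366328 to 103366829), fell (-0.28 ± 0.05), as did a Parvb peak (-0.57 ± 0.11). Camera called the list as higher in the mean (adjusted p = 0.0031, and 0.607 with an estimated correlation), with #2 (0.0232, and 0.669 estimated) and with #4 (0.00203, and 0.507 estimated). The #2 call was lost with quantile scaling (adjusted p = 0.0609), cyclic loess (0.058) and without shMed1 #2 replicate 3 (0.0722). With #2, 159 peaks of the list rose and 57 fell (163 and 58 adjusted over the list alone), and with #4, 128 rose and 24 fell (131 and 26 adjusted over the list alone).

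Of 377 peaks of extracellular matrix genes, 125 rose and 55 fell (129 and 59 adjusted over the list alone), and 108 and 82 with equal totals. Peaks of Tgfbi, a secreted matrix protein (chromosome 13, 56664420 to 56664921), and Col5a1, a collagen V chain (chromosome 2, 27939335 to 27939836), rose by 0.55 ± 0.04 and 0.74 ± 0.06. The gene-end peak of Thbs1, the matrix glycoprotein thrombospondin (chromosome 2, 118127325 to 118127826), fell from 237 ± 9.33 to 91.5 ± 5.58 in #2 and 149 ± 17.1 in #4 (SD, n = 3), and a Col1a1 peak changed by -0.68 ± 0.10. Camera called the list as higher in the mean (adjusted p = 0.0230, and 0.555 with an estimated correlation), with #2 (0.0384, and 0.669 estimated) and with #4 (0.0323, and 0.507 estimated). The call was lost when peaks were assigned to the nearest gene end (adjusted p = 0.102 in the mean, 0.187 with #2 and 0.0844 with #4). The #2 call was also lost with equal totals (0.0504), quantile scaling (0.0609), cyclic loess (0.076), without NTC replicate 3 (0.0669) and without shMed1 #2 replicate 3 (0.0712), and the #4 call without NTC replicate 3 (0.0722) and without shMed1 #4 replicate 1 (0.0574). The list's median with #4 was 0.05, turned to -0.02 with equal totals and was 0.09 without NTC replicate 1. With #2, 133 peaks rose and 69 fell (136 and 70 adjusted over the list alone), and with #4, 95 rose and 30 fell (97 and 31 adjusted over the list alone).

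Of 158 peaks of AP-1 and immediate early genes, which respond first to growth and stress signals, 55 rose and 21 fell (55 and 23 adjusted over the list alone). This excess was absent with equal totals (44 higher and 43 lower), quantile scaling (44 and 45) and cyclic loess (46 and 43). Peaks of Mafk, a small Maf protein (chromosome 5, 139794921 to 139795422), and Fos, an AP-1 subunit (chromosome 12, 85497553 to 85498054), rose by 0.65 ± 0.04 and 0.50 ± 0.04. Gene-end peaks of Ier3 and of Junb, another AP-1 subunit (chromosome 8, 84978472 to 84978973), fell, both by a log2 change of -0.25. Camera called the list as higher in the mean (adjusted p = 0.0282, and 0.769 with an estimated correlation) and with #2 (0.0232, and 0.696 estimated), but not with #4 (0.169), where 41 peaks rose and 24 fell (43 and 24 adjusted over the list alone). With #2, 61 peaks rose and 23 fell (64 and 24 adjusted over the list alone). The calls in the mean and with #2 were lost with equal totals (adjusted p = 0.211 and 0.133), quantile scaling (0.759 and 0.558) and cyclic loess (0.714 and 0.409). The call in the mean was lost without shMed1 #4 replicate 1 (0.113), and the list was called with #4 without shMed1 #4 replicate 3 (0.00583).

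Of 80 peaks of ribosomal protein genes, 13 rose and 31 fell (13 and 31 adjusted over the list alone, 11 and 43 with equal totals), and 17 genes had only lower calls. The gene-end peaks of Rpl3 (chromosome 15, 80083037 to 80083538) and Rpl8 (chromosome 15, 76903863 to 76904364), both proteins of the large subunit, fell by log2 changes of -0.49 ± 0.04 and -0.60 ± 0.06. Intergenic peaks assigned to Rpl3 and Rpl11 rose by 0.49 ± 0.05 and 0.54 ± 0.06, and of all 10 peaks assigned to Rpl3, 7 rose and 1 fell. Camera called the list as lower in the mean (adjusted p = 0.00217, and 0.555 with an estimated correlation), with #2 (0.00698, and 0.669 estimated) and with #4 (0.00239, and 0.507 estimated). With #2, 14 peaks rose and 36 fell (15 and 36 adjusted over the list alone), and with #4, 8 rose and 25 fell (8 and 25 adjusted over the list alone). Among gene-end peaks alone the median log2 change of this list was -0.22 in the mean (adjusted p = 8.04e-05 at the preset correlation). There the medians of the integrin, matrix and AP-1 lists were negative too in the mean (-0.05, -0.10 and -0.04), with none of these called (adjusted p = 0.172, 0.662 and 0.662). With #4 the integrin list on gene-end peaks stayed positive and was called as higher (0.05, adjusted p = 0.0403).

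The remaining lists did not pass camera in any contrast, and those below moved both ways. Of 143 Mediator peaks, 30 rose and 23 fell (adjusted p = 0.852): peaks inside Med13l (0.59 ± 0.04) and Med24 (0.55 ± 0.06) rose, and gene-end peaks of Med25 (-0.61 ± 0.07) and Med22 (-0.44 ± 0.05) fell. Of 150 peaks of dormancy-linked genes, 28 rose and 30 fell (adjusted p = 0.780). Among them, intergenic peaks near Bhlhe40, a circadian repressor (0.58 ± 0.05), and Sox9 (0.36 ± 0.04) rose, and peaks near Cdkn1b, the CDK inhibitor p27 (-0.88 ± 0.11), and the orphan receptor Nr2f1 (-0.40 ± 0.07) fell. Of 151 cell cycle peaks, 23 rose and 37 fell (adjusted p = 0.226). Gene-end peaks of Top2a, a topoisomerase of dividing cells (-0.53 ± 0.06), and Mcm2, a replicative helicase subunit (-0.37 ± 0.05), fell, while peaks inside E2f2 (0.61 ± 0.06) and Cdk6 (0.34 ± 0.04) rose. Adjusted over the list alone, these counts were 30 and 23, 28 and 30, and 23 and 37. With equal totals, adjusted over all peaks, they were 24 and 41, 21 and 50, and 14 and 56.

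Of 227 TGF-beta and BMP signalling peaks, 68 rose and 32 fell (adjusted p = 0.138): peaks of Smad3 (0.73 ± 0.05) and the SMAD repressor Skil (0.58 ± 0.04) rose, and gene-end peaks of Smad7 (-0.26 ± 0.04) and Ski (-0.32 ± 0.06) fell. Of 290 YAP and TEAD target peaks, 75 rose and 33 fell (adjusted p = 0.473). A peak inside Tead4, a YAP partner (0.82 ± 0.05), and a peak inside Myof (0.47 ± 0.04) rose, while an Ajuba peak (-0.46 ± 0.06) and the gene-end peak of Myof (-0.39 ± 0.07) fell. Of 187 mesenchymal peaks, 56 rose and 29 fell (adjusted p = 0.260). Peaks inside Runx2 (0.54 ± 0.03) and Twist2 (0.38 ± 0.04) rose, and peaks of Foxc2 (-0.53 ± 0.08) and Tcf4 (-0.29 ± 0.05) fell. Of 94 epithelial peaks, 24 rose and 16 fell (adjusted p = 0.852): the tight junction genes Tjp1 and Cldn4 (both 0.46 ± 0.05) had peaks that rose, and Krt8 (-0.50 ± 0.07) and Esrp2 (-0.30 ± 0.06) had peaks that fell. Adjusted over the list alone, these counts were 69 and 34, 74 and 33, 56 and 29, and 24 and 17. With equal totals, adjusted over all peaks, they were 56 and 55, 52 and 61, 38 and 44, and 17 and 25.

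Of 132 NF-kappaB and inflammatory peaks, 33 rose and 20 fell (adjusted p = 0.716). An intergenic peak near Csf2, the cytokine GM-CSF (chromosome 11, 54224271 to 54224772), rose from 2412 ± 111 to 4284 ± 203 in #2 and 3159 ± 80.5 in #4 (SD, n = 3), and a peak near Nfkbia rose by 0.50 ± 0.04. Peaks of Csf1 (-0.59 ± 0.10) and Nfkbiz (-0.47 ± 0.08) fell. Of 247 peaks of nuclear receptors, which bind Mediator through MED1, and their targets, 67 rose and 44 fell (adjusted p = 0.635). Peaks of Ppard (0.69 ± 0.04) and the retinoic acid hydroxylase Cyp26b1 (0.73 ± 0.06) rose, and gene-end peaks of Nr1h2 (-0.56 ± 0.07) and Per1 (-0.39 ± 0.07) fell. Of 43 interferon response peaks, 7 rose and 9 fell (adjusted p = 0.473): an intergenic Irf1 peak (0.35 ± 0.04) and an Ifit2 peak (0.26 ± 0.08) rose, and the gene-end peak of Irf1 (-0.19 ± 0.04) fell. The Ifit2 call was lost with equal totals (adjusted p = 0.0666). Adjusted over the list alone, these counts were 33 and 20, 68 and 47, and 7 and 9. With equal totals, adjusted over all peaks, they were 24 and 35, 46 and 67, and 4 and 19.

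Of 70 p53 target peaks, 13 rose and 12 fell (adjusted p = 0.852), including peaks near Btg2 (0.51 ± 0.08) and Pmaip1 (0.33 ± 0.06) that rose and the gene-end peaks of Bax (-0.46 ± 0.07) and Btg2 (-0.21 ± 0.04) that fell. Of 76 unfolded protein and integrated stress response peaks, 16 rose and 12 fell (adjusted p = 0.852). Gene-end peaks of the chaperone genes Pdia4 (0.25 ± 0.03) and Sdf2l1 (0.27 ± 0.04) rose, the former not with quantile scaling (0.01, adjusted p = 0.840), and an Atf6 gene-end peak (-0.54 ± 0.07) and an intergenic Pdia4 peak (-0.32 ± 0.06) fell. Of 54 mammary luminal and basal peaks, 9 rose and 9 fell (adjusted p = 0.852). A Trp63 peak (0.30 ± 0.06) rose, as did the Sox9 peak named above, and Krt14 (-0.28 ± 0.08) and Myh11 (-0.43 ± 0.13) peaks fell. The Myh11 call was lost without NTC replicate 2 (adjusted p = 0.0684) or NTC replicate 3 (0.0744). Adjusted over the list alone, these counts were 13 and 12, 16 and 12, and 9 and 8. With equal totals, adjusted over all peaks, they were 10 and 19, 11 and 25, and 8 and 17.

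Markers of cell types other than carcinoma did not move as groups. Of 24 blood peaks, 4 rose and 4 fell (adjusted p = 0.852), among them peaks of Itgam (0.54 ± 0.09), Ptprc (0.25 ± 0.06 and -0.42 ± 0.11) and Spi1 (-0.28 ± 0.06). Of 70 endothelium and fat peaks, 16 rose and 8 fell (adjusted p = 0.852), among them the gene-end peak of Lep (0.93 ± 0.08) and peaks of Vwf (0.40 ± 0.05), Lipe (-0.33 ± 0.06) and Plin1 (-0.42 ± 0.10). Of 91 neural peaks, 24 rose and 14 fell (adjusted p = 0.852), among them peaks of Mbp (0.45 ± 0.05 and -0.40 ± 0.10), Dlx2 (0.26 ± 0.04) and Slc17a7 (-0.19 ± 0.05). Adjusted over the list alone, these counts were 4 and 4, 16 and 7, and 26 and 16. With equal totals, adjusted over all peaks, they were 3 and 6, 14 and 12, and 15 and 23. The median and camera's direction differed in sign for the mammary (0.02, lower), blood (0.01, lower), endothelium and fat (-0.05, higher) and stress response (0.00, lower) lists, and the mean and camera's direction did for the epithelial (0.00, higher) and Mediator (0.01, lower) lists. More peaks rose than fell in 14 of the 20 lists, and in 5 with equal totals.

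**Figure D3:**
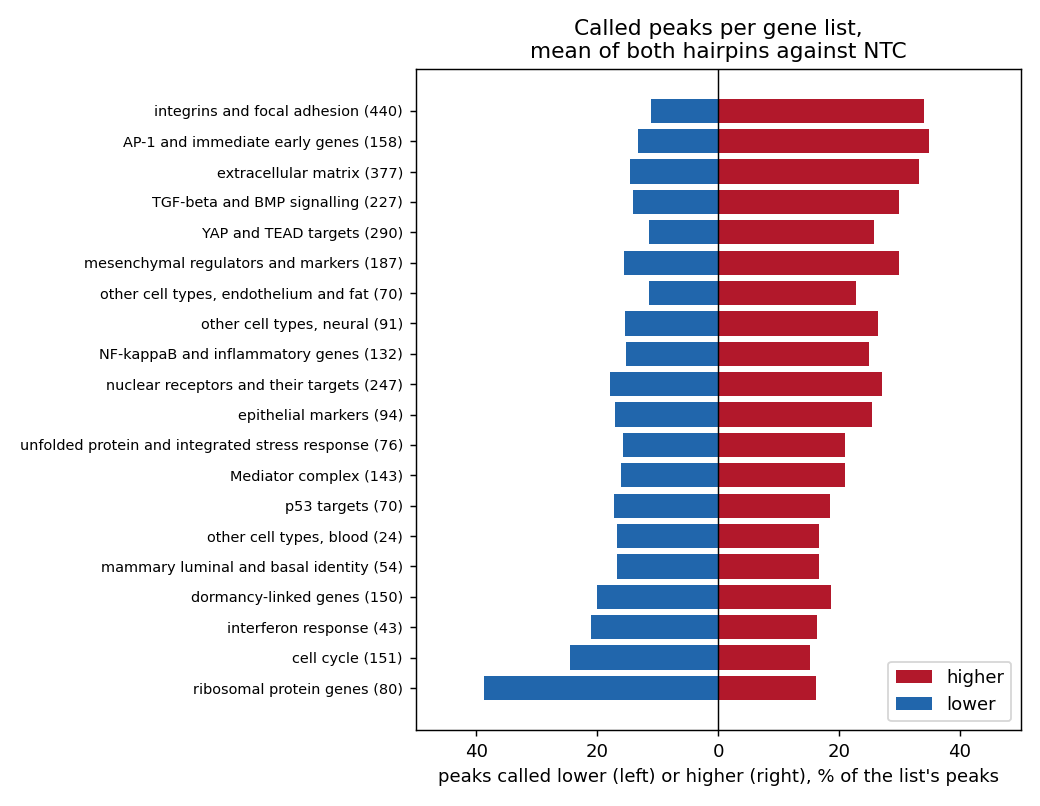
Share of each list's peaks called higher (right bars) or lower (left bars) in the mean of both hairpins against NTC, in percent, with the number of peaks in brackets. Of the integrin and focal adhesion peaks 34.1% rose and 11.1% fell, and of the ribosomal protein peaks 16.2% rose and 38.8% fell, both with the deposited scaling.

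Gene-end peaks and peaks elsewhere moved apart. In the mean of both hairpins, 1755 of 12225 gene-end peaks rose and 3992 fell, while 8538 of 35091 gene-body peaks rose and 4873 fell. With #2, 1473 gene-end peaks rose and 4332 fell, and with #4, 1752 rose and 2755 fell. The mean log2 value of gene-end peaks minus that of other peaks was 1.80 ± 0.02 in NTC, 1.69 ± 0.05 in #2 and 1.75 ± 0.02 in #4 (SD, n = 3). All 6 hairpin libraries lay below all 3 NTC libraries, the closest being #4 replicate 1 (1.7756) and NTC replicate 1 (1.7794). The difference from NTC was -0.11 with #2 and -0.05 with #4 (exact permutation p = 0.10 for each, the smallest possible), and -0.08 for both hairpins (exact permutation p = 0.0476, n = 6 against 3). The median log2 change of gene-end peaks in the mean was -0.07, and stayed negative with equal totals (-0.15), quantile scaling (-0.13) and cyclic loess (-0.13). That of other peaks was 0.01, and turned to -0.06 with equal totals.

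Strong peaks away from gene ends mostly had higher values with the hairpins. Reads outside peaks were not analysed, so a gain of accessibility cannot be told apart from a different signal over background. In the fifth of peaks with the highest mean value, 5620 of 8559 other peaks rose and 585 fell in the mean of both hairpins, while 1303 of 6627 gene-end peaks rose and 2273 fell. More of these other peaks also rose than fell with equal totals (4496 and 1158), quantile scaling (4462 and 1187) and cyclic loess (4324 and 1239). In the fifth of peaks with the lowest mean value, 627 of 14137 other peaks rose and 1382 fell, but this order turned with quantile scaling (1010 and 921) and cyclic loess (1065 and 828).

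**Figure D4:**
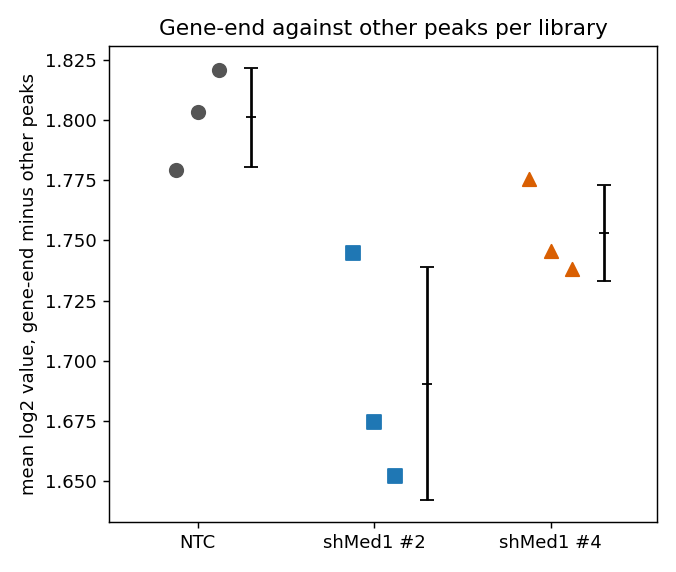
Mean log2 value of gene-end peaks minus that of other peaks (y axis) in each library of NTC, shMed1 #2 and shMed1 #4 (x axis), with the group mean and SD as bars. Values were 1.78 to 1.82 in the 3 NTC libraries and 1.65 to 1.78 in the 6 hairpin libraries, all below NTC.

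The hairpins also differed from each other, which asks what is particular to each hairpin. Against #2, 6439 peaks were higher with #4 and 9897 lower (21.5% of those tested). A log2 difference of at least 1 was reached by 528 of them, 350 higher and 178 lower, so the balance turned there. A gene-end peak of Meis2, a homeobox gene (chromosome 2, 116066904 to 116067405), was at 69.4 ± 15.2 in NTC, 32.4 ± 4.66 in #2 and 118 ± 15.8 in #4 (SD, n = 3), a log2 difference of 1.84 (limma, adjusted p = 3.3e-09). Peaks inside Sash1, Csmd3 and Rbms3, an RNA-binding protein, were higher with #4 by 1.63 to 1.70. A peak inside Mapk4, an atypical MAP kinase (chromosome 18, 73947934 to 73948435), was at 135 ± 18.5 in NTC, 299 ± 21.3 in #2 and 88.9 ± 9.35 in #4, a log2 difference of -1.74 (limma, adjusted p = 6.46e-14). Peaks assigned to Myl10, Nalcn, a sodium leak channel, Cobl, an actin nucleator, and Sh3rf1 were lower with #4, with differences from -1.67 to -1.47, and an unassigned peak (chromosome 10, 56921107 to 56921608) was higher by 1.74. Of gene-end peaks, 1409 were higher with #4 and 452 lower, but over libraries the hairpins overlapped in gene-end minus other peaks (difference 0.06, exact permutation p = 0.20, n = 3 against 3). With quantile scaling they did not overlap (0.08, exact permutation p = 0.10, the smallest possible). Camera called 0 of 20 lists, and 0 at an unadjusted p under 0.05, while the AP-1 list was called lower without shMed1 #4 replicate 1 (adjusted p = 0.0394).

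Whole chromosomes moved little. Chromosome 10 had the median farthest from 0 with #2 (-0.04), chromosome 18 with #4 (-0.05) and in the mean (-0.04), and chromosome 9 in #4 against #2 (0.06).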

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

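The counts over other splits of the 6 libraries of a pair of groups, the test within the strongest peaks, the thinning of reads and the tests on neighbouring peaks were chosen after the results were seen.

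Both hairpins target Med1, yet their effects differed between groups under a direct test: limma called 16336 of 75930 peaks in #4 against #2. Of these, 575 were called against NTC in opposite directions, 313 higher with #2 and lower with #4, and 262 the other way, with peaks of Meis2, Rbms3, Mapk4, Myl10 and Nalcn among them.

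For #4 against #2, the real split gave 16336 peaks and the highest of the other splits 0 (3887 at an unadjusted p under 0.05). For #2 against NTC the values were 32709 and 0 (5448 unadjusted), and for #4 against NTC 22302 and 0 (4002 unadjusted). In each, 1 of 10 splits, the real split, gave as many, and 10 splits are too few for a share under 0.05. For the mean of both hairpins, 1 of 100 drawn splits of the 9 libraries, the real split, gave as many as 30248 peaks. That share is the smallest 100 splits can give, and it argues against libraries that do not differ by group. It cannot tell hairpins against NTC from any other difference between the 3 groups. The highest of the other splits gave 27034. That split points to the structure of the samples, as do all 9 of the other 99 splits with any call, since each kept a group of the study whole.

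Gene-end peaks were lower against other peaks in all 6 hairpin libraries, by 0.08 on the log2 scale in the mean. Counting noise from unequal depth is argued against, since the difference was -0.07973 after every library was thinned to the smallest (exact permutation p = 0.0476). Thinning keeps the expected value of each peak, so it cannot test other effects of depth. A single deviating library is argued against, since 87.69% of the difference was left in the smallest case, without NTC replicate 3. Leaving out 1 library cannot test a difference that changes with the replicate number. Gene-end minus other peaks was 1.7794 in NTC, 1.7447 in #2 and 1.7756 in #4 for replicate 1. For replicate 3 these values lay further apart, at 1.8207, 1.6519 and 1.7381. A trend with peak strength alone is argued against, since the difference was -0.2321 among the fifth of peaks with the highest mean value (exact permutation p = 0.0119, the smallest possible), although it was 0.02 in the fifth with the lowest. Other effects of depth, GC content and a different signal over background were not tested and stay open, so neither a technical nor a biological explanation is preferred.

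Peaks within the same 1 Mb of a chromosome moved together. A trend with peak strength and place is argued against: the SD of window medians was 0.098 in the mean of both hairpins, above 0.068 to 0.0743 in 100 shuffles within strength and place classes. A copy number difference would move gene-end peaks as much as the others. Only 1 window of the mean lay beyond every shuffle and it held 0 gene-end peaks, so the test was recast. Of 1208 windows with enough gene-end and other peaks, it took the 61 that moved most in alternate other peaks. The windows beyond every shuffle were not among these and stay untested. In the 61 windows the remaining other peaks moved by only 0.0897 with #4 and 0.0782 in the mean. There gene-end peaks moved by 0.315 of the shift of the remaining other peaks with #4 (95% bootstrap interval -0.0444 to 0.701). In the mean the ratio was 0.314 (-0.0202 to 0.765). Both ratios argue against copy number as the whole cause there. With #2 the ratio was 0.698 (0.36 to 1.44), and in #4 against #2 it was 0.686 (0.36 to 1.3). These intervals hold 1 as well as far lower ratios, so copy number stays open there. GC content and a different signal over background were not tested for neighbouring peaks, so no other cause is preferred.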

How the results depend on the processing

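The voom weights, the thinned reads and the assignment to the nearest gene end were tried after the data were seen. Totals of changed peaks (both directions) stayed within 1.5 times under every setting run except the fold minimum, at 25761 to 35768 with #2, 15773 to 25246 with #4, 21958 to 34229 in the mean, 12701 to 16925 in #4 against #2 and 10356 to 17599 in both hairpins. A log2 change of at least 1 left 444, 199, 93, 528 and 41, by construction. Lower calls alone moved more: without NTC replicate 3 they went from 9152 to 5500 with #4, 13452 to 8325 in the mean and 5909 to 3193 in both hairpins, and without NTC replicate 2 to 5819 with #4 and 3658 in both. Equal totals raised these to 14938, 21010 and 10751. Of 2780 values of 143 named peaks, 2771 kept their direction and side of the threshold, 4 lost and 5 gained a call, and 0 turned.

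Camera called 4 lists with #2, but 2 with equal totals, 1 with quantile scaling, 1 with cyclic loess and 1 on gene-end peaks, and 2 to 4 with a library left out. It called 4 in the mean, but 1 on gene-end peaks, 3 with #4, but 2 on gene-end peaks, and 0 in #4 against #2, with 0 to 1 left out. An estimated correlation left 0 calls with #2, 0 with #4 and 0 in the mean. On gene-end peaks alone, list medians turned for AP-1 (-0.04822 with #2, -0.04099 in the mean), extracellular matrix (-0.1391 with #2, -0.03475 with #4, -0.1015 in the mean) and integrins (-0.08351 with #2, -0.04991 in the mean). With equal totals the matrix median with #4 was -0.01676. The correlation of both hairpins was 0.5585 to 0.6444 with a library left out. Without gene-end peaks, the medians of the same chromosomes were -0.008085 (chromosome 10, #2), -0.04565 and -0.02556 (chromosome 18, #4 and mean) and 0.04481 (chromosome 9, #4 against #2). The cause was not tested for these.

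Over all peaks, same-numbered libraries showed no shared deviation: their deviations correlated at -0.0843 to 0.0335 over 9 pairs. That check cannot see a group difference that changes with the replicate number, as in the gene-end values above. With the number as a block, 31867, 21286, 29503, 15393 and 14499 peaks were called, with 4, 3, 4 and 0 lists, and no list call changed. Models on whole reads in edgeR and DESeq2 were not run, since the reads could not be checked, nor were motif classes or matching on GC content, and fits of the compared groups only gave no value for the mean or for both hairpins. Thinning every library to the smallest left 31118 calls with #2, against 32709. The median standard error of a log2 fold change per hairpin was 0.12. Simulated folds of 1.5 were found in 74% of peaks, with far fewer changed peaks than in the data.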

Other observations

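The genes, windows and their tests below were chosen after the results were seen.

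Some genes with 10 or more assigned peaks moved nearly as a whole in the mean of both hairpins. In 27 of 1502 such genes at least 70% of peaks rose, against at most 8 in 100 shuffles of calls within strength and place classes. These shuffles spread calls over the genome, whereas neighbouring peaks moved together. The excess therefore cannot tell a change of a single gene from one of a wider stretch. Among them, 10 of 12 peaks rose at Socs3, which restrains cytokine signalling, 10 of 13 at Bhlhe40, a circadian repressor, 7 of 10 at Hes1, a Notch-responsive repressor, 20 of 26 at the tetraspanin Tspan9, and 7 of 10 at Col6a2, a collagen VI chain. Timp2, an inhibitor of matrix metalloproteinases, had 10 of 14, and S100a10, a partner of annexin A2, had 10 of 13. With equal totals the numbers that rose were 6 at Socs3, 9 at Bhlhe40, 6 at Hes1, 16 at Tspan9, 6 at Col6a2, 9 at Timp2 and 9 at S100a10, and 5 of the 27 genes reached 70%. The shuffles were not redone with that scaling.

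In 4 genes at least 70% of peaks fell, against at most 1 in the shuffles, with the same limit. These were Abt1 with 10 of 11, Trim27 with 9 of 12, Gas7 with 9 of 12 and Ccser2 with 7 of 10. With equal totals, 11, 11, 10 and 7 fell at these genes, and with cyclic loess 10, 8, 6 and 7.

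With #4, 3 stretches of 1 Mb lay beyond every shuffle, and with #2, 0 did. The 3 stretches held 0 gene-end peaks, so a copy number difference could not be tested there. On chromosome 12, from 92 to 93 Mb, the median log2 change was 0.71 with #4, and 0.51 in the mean, also beyond every shuffle. On chromosome 9, from 117 to 118 Mb, a stretch with Rbms3, it was 0.62 with #4 but -0.49 with #2. In #4 against #2 it was 1.18, also beyond every shuffle. On chromosome 18, from 16 to 17 Mb, a stretch with peaks assigned to the cadherin gene Cdh2, it was -0.58 with #4. There 9 of 11 peaks fell, and the stretch passed in no other comparison.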
